A study of Homo sapiens with 25 samples.

How the data were processed

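Total RNA from primary human coronary artery endothelial cells, in 5 groups of 5 samples, was reverse transcribed with MegaPlex primer pools, preamplified, and run on TaqMan microRNA array cards (pool A with 377 and pool B with 373 microRNAs) on a real-time PCR system, per the labels' protocols. Each deposited file gives 1 value for each of 740 assays, or none. The values the authors deposited are a linear ratio of each assay to a reference, of the form 2 to the power of minus the difference in threshold cycle. This form is read from the values, and the reference, the limit for a missing value and the treatment of repeated wells are not given in the sources used here. No threshold cycles and no small-RNA control assays are among the values used. Levels are given as log2 of the ratio, so that 1 unit is 1 cycle or a 2-fold difference if amplification doubles at each cycle.

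The log2 values lay close to steps of 1 cycle: in 23 of 25 samples over 90% of the values were within 0.1 cycle of a step in each card set. The resolution of a single value is therefore about 1 cycle. The exceptions were set A of rHDL 2 (23.7% of values) and set B of SUV 5 (26.0%). The position of the steps differed between 2 groups of assays within a sample, which allowed the assays to be assigned to 2 card sets (277 in set A, 204 in set B, 259 in neither, of which 161 were measured in no sample) by a circular 2-means clustering in 4 samples. The assignments from 3 of these samples matched those from the first in 340 of 341, 329 of 329 and 344 of 345 assays. The card sets are an inference from the values and are not named in the files.

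The comparisons were made with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a variance trend) on the log2 values as deposited, over 23 samples in 5 groups, with 2-sided tests, Benjamini-Hochberg adjustment over the assays tested and a threshold of 0.05. An assay entered if it was measured in at least 80% of the samples of 1 group, and a comparison of it was tested if at least 2 samples of each group compared were measured (415 assays entered). Missing values stayed missing. Changes after card-mean scaling were computed in the same model, with each sample centred on the mean of the assays measured in all samples, separately for each card set. A constant shift per sample and card cancels in this scaling. The planned scaling of threshold cycles also had a limit on the normalising assays, averaged wells and a floor, which could not be applied. Here the card sets are inferred as well, so the planned scaling need not have given the same values.

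The main design was fixed before the data were examined, and several points departed from it. It named all 25 samples, and PBS 1 and SUV 1 were left out because their files are identical and nothing in the labels says which is right, which was decided before any comparison was fitted. It set missing wells to a floor threshold cycle, which cannot be done without threshold cycles. The requirement of 2 measured samples in each compared group was added after exploratory fits (4, each of which called only miR-223 in native HDL against PBS). The design provided for values that the authors had already normalised to be used as deposited, which was done. Card-mean scaling beside them, and the alternatives for the identical files, the lowest values and the doubted samples (rHDL 2, rHDL 4 and native HDL 1), were chosen after seeing the data. The list tests were first computed on card-mean scaled values and then set to the deposited values that the design names. They were planned for lists with at least 3 tested members, but used only members assigned to a card set and measured in every sample used.

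Gene lists (21, fixed before the data were examined) were tested with camera at a preset correlation of 0.01, and with camera at an estimated correlation and with fry as alternatives, for lists with at least 3 members assigned to a card set and measured in every sample used, with adjustment over the lists (18 of 21). As deposited the estimated correlation within a list had a median of 0.68 (largest 0.83), far above the preset. Camera p-values at the preset are therefore too small as deposited. Camera compares the mean statistic of a list with that of the other assays, so 1 large change can set its direction. The direction can then differ in sign from the list's median, as in the NF-kB and lipid lists with native HDL (upward, medians −0.35 and −0.16). Both lists hold miR-223, and both medians lie below the median of −0.13 over all assays tested. The lists held HDL-associated, endothelial-enriched, angiogenesis, NF-kB and adhesion, lipid metabolism, shear-stress, p53, hypoxia and cluster or family microRNAs, and markers of blood, liver, muscle, fibroblast and epithelial cells. The named assays follow a rule fixed before the data were examined. For a comparison with PBS, it took every assay past the threshold up to 10 in each direction, the 5 smallest unadjusted p in each direction where fewer than 10 passed, the 2 smallest p of each list with a call, and miR-223, miR-126, miR-146a, miR-21 and miR-222 in any case. Between treatments it took up to 5 in each direction that passed, or the 2 smallest p in each direction where fewer than 4 passed. Other assays named in the detection tests, in the HDL and blood-cell lists and among the most abundant were chosen after their values were seen. Single values (miR-223, mean levels) were compared by exact permutation tests, and presence by Fisher's exact test.

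The fit was tested on simulated data for native HDL against PBS over 414 assays. Noise was normal and independent between assays, beside the samples' own card shifts. Stray values and other shared deviations of the real samples were thus not imitated, and recovery there can differ. With many assays changed at once, in 1 simulated data set, the fit recovered 0 of 17 changes of 1 log2 unit, 3 of 22 of 2 and 18 of 19 of 4 as deposited. After card-mean scaling it recovered 3 of 17, 15 of 22 and 19 of 19, with 3 false calls among 347 unchanged assays. With 1 assay changed at a time in 15 runs, a change of 4 was recovered in 13 runs as deposited and in 15 scaled, a change of 2 in 0 and 6, and a change of 1 in none. A 4-fold change (2 log2 units) of 1 assay alone was thus mostly missed, more so as deposited than after scaling. With many assays changed at once, most changes of that size were recovered after scaling. The median 95% interval for native HDL against PBS reached 1.76 log2 units to each side as deposited and 0.97 scaled. Alternatives covered the normaliser, missing and low values, the filter, the replicate block, the variance model, the samples used and leaving out each sample in turn. Each count was also set beside other splits of the same samples (at most 100). Figures were drawn with matplotlib.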

Results

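MicroRNA levels were measured by TaqMan array-card RT-PCR in primary human coronary artery endothelial cells, which line the arteries of the heart. In every group the cells were of passages 3 to 6, with 5% serum, per the labels' protocols. They were incubated for 16 to 24 h with phosphate-buffered saline (PBS, the control) or with 1 of 4 preparations. Native HDL is the high-density lipoprotein particle of plasma (1 mg/ml total protein). Reconstituted HDL (rHDL) is a particle assembled from apolipoprotein A-I, the main HDL protein, and phospholipid (1 mg/ml apolipoprotein A-I). Lipid-free apolipoprotein A-I (apoA-I) was given at 1 mg/ml, and small unilamellar vesicles of the phospholipid PLPC (SUV) at 3 mmol/L. The labels give 5 biological replicates per group. The sources used here do not say whether these came from separate cultures or donors, so p-values measure the spread between these samples only. The stated purpose was to compare each treatment with PBS, and the set of preparations separates the plasma particle from its assembled form, its protein and its lipid.

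Each sample had a value for 361 to 453 of 740 assays, and 296 assays were measured in all 25 samples. The files of PBS 1 and SUV 1 held the same values (420 of 420 equal), while no other pair of samples shared more than 1 value. Both were left out of the comparisons, which leaves 4 PBS and 4 SUV samples and 5 of each other group. The most abundant microRNA in the PBS samples was miR-126, an endothelial microRNA of vascular integrity, at a log2 relative level of −0.12 ± 0.06 (SD, n = 4). This SD is below the resolution of about 1 cycle, and the left-out PBS 1 file had miR-126 at −1.12. After miR-126 came miR-24 (−1.38 ± 0.46), miR-222, a regulator of endothelial growth and KIT (−1.59 ± 0.58), and miR-106a of the miR-17 family (−3.35 ± 0.46). The next places were held by miR-19b, miR-17, miR-100, miR-99a, miR-31 and miR-21, between −3.37 and −4.10.

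The mean log2 level over the commonly measured assays was −11.84 ± 0.18 with PBS (SD, n = 4), −11.95 ± 0.91 with native HDL (n = 5), −11.00 ± 1.62 with rHDL (n = 5), −12.14 ± 0.73 with apoA-I (n = 5) and −11.98 ± 0.59 with SUV (n = 4). None of these differences from PBS, nor those in the number of assays measured, passed an exact permutation test (2-sided, adjusted p = 1 in each of 8 tests). With groups of this size a single difference could not have passed after adjustment over 8 tests. Single samples stood apart: rHDL 4 had a mean of −8.65, rHDL 2 of −9.99 and native HDL 1 of −10.66. In rHDL 2 the shift lay in 1 of the 2 array-card sets, at −8.19 in set A against −13.21 in set B. The lowest means were −13.27 in apoA-I 3, −12.92 in native HDL 5 and −12.83 in SUV 4. The identical PBS 1 and SUV 1 files, left out here, had −12.35, below each PBS sample that was kept. As deposited, the median assay changed from PBS by 0.79 with rHDL, −0.13 with native HDL, −0.30 with apoA-I and −0.26 with SUV. Changes are therefore also given after each sample was centred on the mean of its commonly measured assays per card set (card-mean scaling), which brought these medians to −0.02, −0.00, 0.04 and −0.02.

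**Figure D1:**
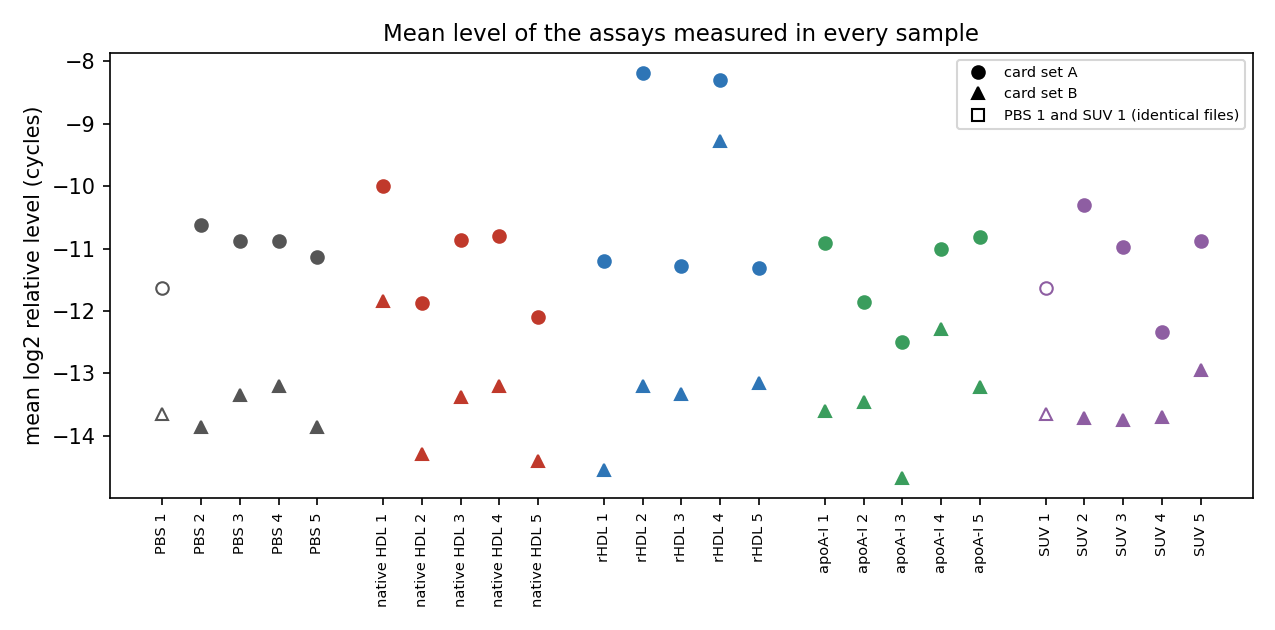
Mean log2 relative level (cycles) of the commonly measured assays in each of the 25 samples, with circles for card set A, triangles for card set B and open symbols for the identical PBS 1 and SUV 1 files. Both sets of rHDL 4 and native HDL 1 lie above most other samples, while rHDL 2 is high in set A (−8.19) and not in set B (−13.21).

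Native HDL raised miR-223, a microRNA abundant in myeloid cells and known as cargo of plasma HDL (gene MIR223, NCBI gene 407008). Its log2 relative level was −14.46 ± 1.32 with native HDL (SD, n = 5) against −18.36 ± 1.00 with PBS (n = 4). The difference was 3.90 (SE 0.88, 95% interval 2.14 to 5.66), a 14.9-fold higher level, with an adjusted p of 0.0194 in limma. After card-mean scaling it was 4.15 (interval 3.16 to 5.13), or 17.7-fold, with an adjusted p of 3.66e-06. All 5 native HDL samples lay above all 4 PBS samples, and miR-223 moved from rank 286 to rank 197 among 297 assays ordered by mean level. An exact permutation test of miR-223 alone gave p = 0.0159 (adjusted p = 0.0635 over 4 treatments). The test doubles the smaller tail, and this is the smallest p it allows for 5 against 4 samples. A single treatment could therefore not have passed after adjustment, whatever its values. miR-223 was measured in every sample, so presence against absence could not differ.

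**Figure D2:**
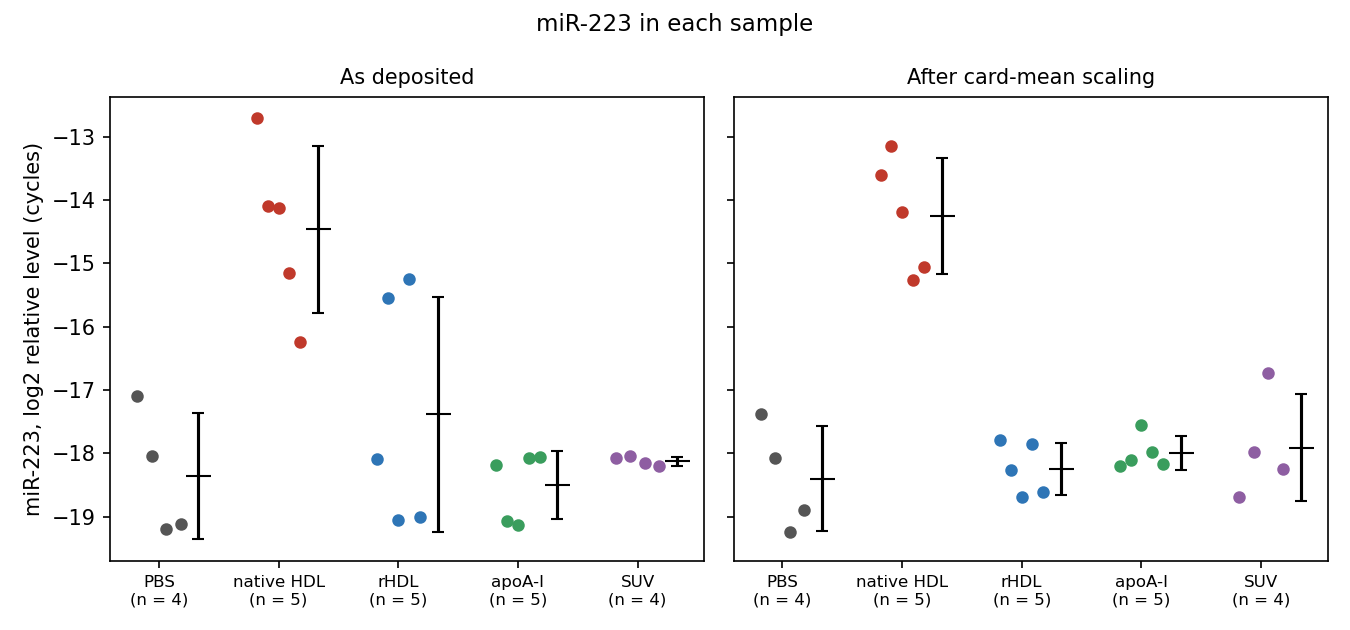
Log2 relative level of miR-223 (cycles) in each sample, as deposited on the left and after card-mean scaling on the right. Points are samples, and bars give the mean ± SD of each group. The native HDL samples lie between −16.25 and −12.70 as deposited, against −19.20 to −17.09 with PBS, and the high values of rHDL 2 and rHDL 4 on the left fall back to the other rHDL samples on the right.

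miR-223 was the only 1 of 406 assays tested to pass in native HDL against PBS, with both scalings (406 and 405 tested). Of the assays 0.25% had an unadjusted p under 0.05 as deposited, less than the 5% that chance gives for independent assays. The spread is estimated over all 5 groups, including the shifted rHDL 2 and rHDL 4, which makes the main test more cautious. The SE of miR-223 was 0.88, against 0.72 with only the groups compared and 0.64 without rHDL 2, rHDL 4 and native HDL 1. As deposited the call was lost in 6 of the 9 fits that left out 1 sample (PBS 3, PBS 4, PBS 5, native HDL 1, native HDL 2 or native HDL 3; differences from 3.46 to 4.34, adjusted p up to 0.208). It was also lost when missing values were set to the sample's lowest value (adjusted p = 0.0579) and by an ordinary 2-sample test (adjusted p = 0.743), while after card-mean scaling it held in 9 of 9 such fits (adjusted p up to 5.35e-05).

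The other assays with the smallest p did not pass, with an adjusted p of 0.996 for the next assay after scaling. The higher ones were miR-375, known from pancreatic islets and epithelia, at 1.83 (2.14 scaled), miR-1249 at 1.67 (1.23 scaled), miR-601 at 1.40 (1.45 scaled) and miR-129-3p at 1.43 (1.54 scaled). The lower ones were miR-135a at −1.79 (−1.26 scaled), miR-335 at −1.26 (−1.01 scaled), miR-23a* at −1.26 (−1.004 scaled), miR-296-3p at −1.31 (−0.78 scaled) and miR-885-5p at −1.31 (−0.87 scaled). Endothelial and inflammatory microRNAs fixed for reporting also did not pass. miR-126 was at −0.57 (−0.32 scaled), miR-146a, which restrains NF-kB signalling, at −0.71 (−0.46 scaled), miR-21 at −0.77 (−0.53 scaled), and miR-222 at −0.26 (−0.01 scaled, and 0.26 when medians per card set were used). Leaving out 1 sample brought miR-375 to 1.04, miR-23a* to −0.52, miR-296-3p to −0.78, miR-885-5p to −0.79, miR-146a to −0.45, miR-21 to −0.18 and miR-222 to 0.0555.

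Of the 11 tested members of the HDL-associated list, miR-223 rose and 10 did not pass, and the count was the same when adjusted over the list alone. miR-375 had the second-smallest p of the list, at 1.83 (2.14 scaled, interval 0.48 to 3.80, adjusted p = 0.996). miR-150 was at 0.46 (0.71 scaled), miR-486-5p at 0.09 (0.43 scaled), miR-92a at −0.22 (0.03 scaled) and miR-24 at 0.09 (0.34 scaled). The list passed camera (adjusted p = 0.0483, upward; 4.02e-04 scaled), and its call was lost with an estimated correlation (adjusted p = 0.99; 0.151 scaled). The blood-cell list of myeloid and lymphoid microRNAs, which shares miR-223, miR-150 and miR-146a with it, had 1 of 8 tested members higher, again miR-223, also when adjusted over the list alone. It passed camera (adjusted p = 0.021; 0.00172 scaled), with an adjusted p of 0.99 with an estimated correlation as deposited and 0.0187 scaled. As deposited the HDL-associated list was not called without PBS 3, PBS 4, native HDL 1, native HDL 2, native HDL 3 or native HDL 5, and the blood-cell list, whose median was −0.01 (0.24 scaled), was not called without PBS 3, PBS 4, native HDL 1 or native HDL 5. Neither list passed once miR-223 was taken out, with adjusted p of 0.992 and 0.912 as deposited and 0.901 and 0.953 scaled. Lymphocyte-rich miR-342-3p was at 0.09 (0.34 scaled) and miR-155 at −0.11 (0.14 scaled). Of the blood-cell microRNAs at low level, miR-142-3p was measured in 3 of 5 native HDL and 1 of 4 PBS samples. With rHDL it was measured in 1 of 5, with apoA-I in 3 of 5 and with SUV in 2 of 4. Erythroid miR-451 was measured in 2 of 5 native HDL and 3 of 4 PBS samples, and miR-144 and liver miR-122 in none of either group. miR-363, which is on the erythroid list and also belongs to the miR-106a cluster, was measured in 4 of 5 native HDL and 0 of 4 PBS samples, and in 3 of 5 with rHDL, 2 of 5 with apoA-I and 1 of 4 with SUV.

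miR-223 was also the only called member of the NF-kB and adhesion-molecule list (1 of 13 tested) and of the cholesterol and lipid metabolism list (1 of 17 tested). In the former miR-9 was at −0.87 (−0.62 scaled, and −0.42 without native HDL 5) and did not pass. These lists and the others tested, 16 in all, did not pass camera (smallest adjusted p = 0.309). The 12 endothelial-enriched microRNAs had a scaled median of −0.11 and the 20 angiogenesis microRNAs one of −0.02. The scaled median was −0.11 in the miR-17-92 family clusters, −0.14 in their passenger strands, −0.09 in the let-7 family, −0.16 in the miR-23-27-24 clusters, 0.06 in the miR-29 and miR-30 families, −0.08 in the shear-stress list, −0.09 in the p53 and senescence list, 0.03 in the hypoxia and redox list and 0.08 in the DLK1-DIO3 cluster. In the lists of other cell types it was 0.14 for erythroid, 0.09 for liver, −0.08 for smooth muscle and fibroblast, and 0.04 for epithelial microRNAs. The C19MC cluster had 1 tested member, at 0.99 (1.24 scaled), and the small-RNA controls had none.

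**Figure D3:**
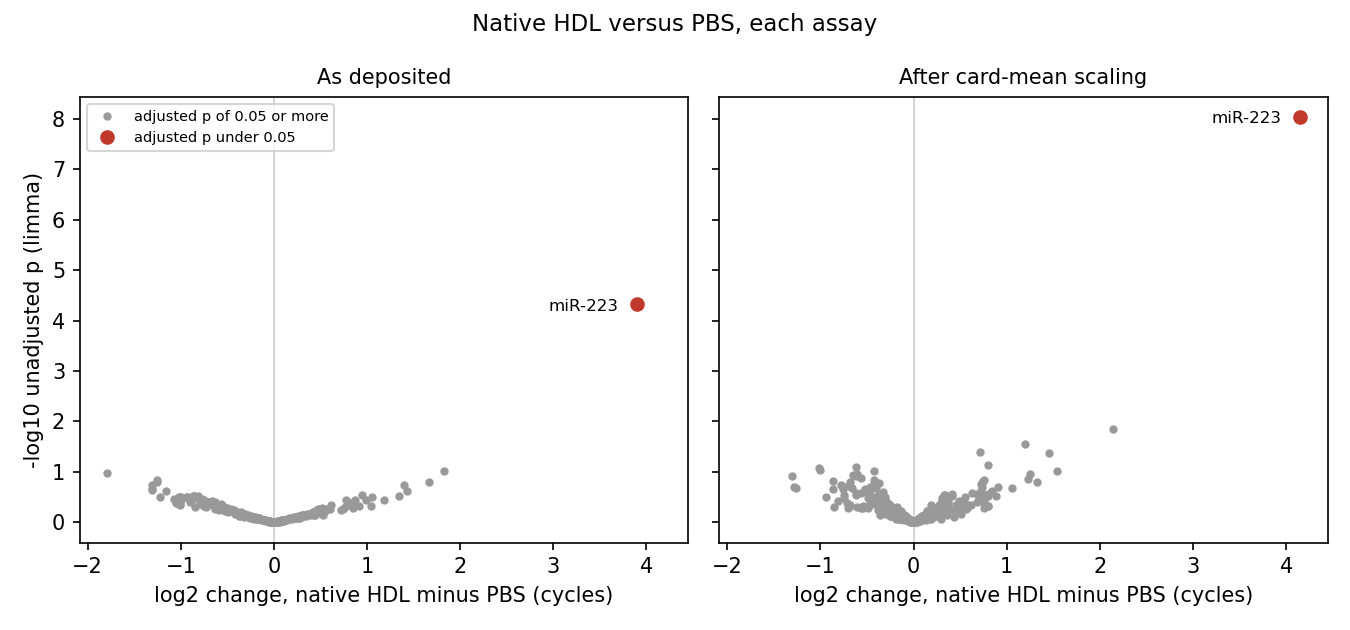
Log2 change between native HDL and PBS (cycles, horizontal) against −log10 of the unadjusted limma p (vertical) for each tested assay, as deposited on the left and after card-mean scaling on the right. The single red point is miR-223 (3.90 and 4.15), the only assay with an adjusted p under 0.05 in either panel.

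With rHDL against PBS no assay passed in limma (0 of 406 tested, 2 or 0.49% at an unadjusted p under 0.05, and 0 by an ordinary 2-sample test). miR-223 was at 0.97 (interval −0.79 to 2.74), and at 0.16 (−0.83 to 1.14) after card-mean scaling. Its difference between native HDL and rHDL was tested directly and is given below. The smallest p belonged to miR-375 at 2.42 (1.60 scaled), miR-187 at 1.92 (1.10 scaled), embryonic-stem-cell miR-302b at 2.16 (1.54 scaled), miR-182 at 2.14 (0.93 scaled) and miR-1301 at 1.73 (0.87 scaled). The lower ones were miR-638 at −2.04 (−1.62 scaled), miR-1183 at −2.17 (−1.59 scaled), miR-374a* at −1.08 (−0.996 scaled), miR-654-5p at −0.84 (−1.66 scaled) and miR-486-3p at −1.04 (−1.68 scaled). The sign of miR-126 (0.16; −0.66 scaled) and of miR-21 (0.34; −0.48 scaled) depended on the scaling, while miR-146a was at 1.34 (0.52 scaled) and miR-222 at 1.20 (0.39 scaled). Leaving out rHDL 4 brought miR-182 to 1.22, miR-1301 to 0.67, miR-654-5p to −0.33, miR-146a to 0.64, miR-222 to 0.41, miR-126 to −0.27 and miR-21 to −0.0421. Leaving out rHDL 2 brought miR-302b to 0.59 and miR-486-3p to −0.46, miR-638 was at −1.05 without rHDL 1, and miR-374a* at −0.59 without PBS 3. No member of any list passed, also when adjusted over the list alone, and none of 18 lists passed camera (smallest adjusted p = 0.631). Scaled list medians ran from −0.46 (erythroid) to 0.29 (smooth muscle and fibroblast). All values before scaling carry the shift of rHDL 2 and rHDL 4, and without these samples and native HDL 1 the values of miR-182, miR-223, miR-126, miR-146a, miR-21 and miR-222 were below 0. Those of miR-638, miR-1183, miR-374a* and miR-486-3p were above 0 when missing values were set to the sample's lowest value.

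With lipid-free apoA-I no assay passed in limma (0 of 407 tested, 1 or 0.25% at an unadjusted p under 0.05, and 0 by an ordinary 2-sample test). This share too is under the 5% that chance gives for independent assays, in a fit whose spread includes rHDL 2 and rHDL 4. miR-223 was at −0.14 (interval −1.90 to 1.62) and, after scaling, at 0.40 (−0.59 to 1.39). The smallest p among lower assays belonged to miR-216a at −1.77 (−1.23 scaled), miR-654-5p at −1.79 (−1.25 scaled), epithelial miR-200b at −1.61 (−1.07 scaled), miR-17* at −1.79 (−1.90 scaled) and collagen-targeting miR-29b at −1.60 (−1.06 scaled). Among higher assays they were miR-1249 at 1.31 (0.96 scaled), miR-1227 at 1.09 (0.97 scaled), miR-374b* at 1.19 (0.65 scaled), miR-656 at 0.97 (0.85 scaled) and miR-1282 at 1.03 (1.20 scaled). Without apoA-I 4 miR-1227 was at 0.30 and miR-654-5p at −1.05, and without PBS 2 miR-1282 was at −0.0752 and miR-656 at 0.54. miR-126 was at −0.60 (−0.05 scaled), miR-21 at −0.81 (−0.27 scaled), miR-222 at 0.11 (0.65 scaled), and miR-146a at −0.15 (0.39 scaled, with the sign turned). With 1 sample left out these came to −0.24, −0.48, −0.25 and 0.26. No list member passed, also when adjusted over the list alone, and no list passed camera (smallest adjusted p = 0.159). After scaling the nearest was the HDL-associated list (adjusted p = 0.0547, upward), which had an adjusted p of 0.822 with an estimated correlation.

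With SUV no assay passed in limma (0 of 403 tested, 5 or 1.24% at an unadjusted p under 0.05). An ordinary 2-sample test called 1, miR-26a-2* (1.00). miR-223 was at 0.24 (interval −1.62 to 2.10) and at 0.49 (−0.55 to 1.53) after scaling. The higher assays with the smallest p were miR-1293 at 7.18 (7.11 scaled), miR-187 at 1.504 (1.75 scaled), miR-601 at 1.48 (1.65 scaled), miR-26a-2* at 1.00 (0.96 scaled) and miR-148b* at 0.76 (0.72 scaled). The value of miR-1293 came from SUV 4 alone (log2 level 8.56 against a median of −18.15 in the other samples), and was −2.33 without it. The lower ones were miR-661 at −3.08 (−2.89 scaled), miR-376c at −2.31 (−2.06 scaled), muscle miR-133a at −2.06 (−1.81 scaled), miR-516-3p at −2.40 (−2.50 scaled) and miR-663B at −1.88 (−1.99 scaled). SUV 5 had low miR-376c (−19.41 against a median of −11.08 in the other samples) and miR-661 (−21.20 against −13.25), and without it their changes were −0.23 and −0.59. Without SUV 5 the changes of miR-516-3p, miR-663B and miR-148b* were −0.35, −0.30 and 0.44, and miR-133a was at −1.36 without PBS 3. miR-126 was at −0.27 (−0.02 scaled), miR-146a at −0.51 (−0.27 scaled), miR-21 at −0.54 (−0.29 scaled), and miR-222 at −0.01 (0.24 scaled), and leaving out 1 sample brought them to −0.00805, −0.12, −0.0317 and 0.51.

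One list passed camera with SUV, the DLK1-DIO3 cluster of imprinted microRNAs, downward (adjusted p = 0.00607). That p-value uses the preset correlation of 0.01, while the median estimated correlation within the lists was 0.68 as deposited, so it is too small. The adjusted camera p was 0.969 with an estimated correlation and 0.0857 after card-mean scaling. None of its 46 tested members passed, also when adjusted over the list alone. Its median of −0.28 (−0.26 scaled) was close to the median of −0.26 over all assays tested as deposited, while after scaling that median was −0.02. Of the members 38 were below 0 (35 scaled), and the 2 with the smallest p were miR-376c and miR-432* (−1.67; −1.62 scaled). The list no longer passed without SUV 5 or without PBS 2. Without SUV 5, miR-432* was at 0.22. None of the 17 other lists passed (smallest adjusted p = 0.178).

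The differences between treatments were tested directly. miR-223 was higher with native HDL than with apoA-I (4.04, adjusted p = 0.00439 in limma; 3.75 scaled, adjusted p = 7.96e-06) and than with SUV (3.66, adjusted p = 0.0477; 3.66 scaled, adjusted p = 3.27e-05). Against rHDL it was at 2.92 (adjusted p = 0.361) and did not pass as deposited. After card-mean scaling it was at 3.99 (interval 3.06 to 4.92, adjusted p = 2.56e-06), and it passed as deposited without rHDL 4 (3.46, adjusted p = 0.0185). Scaled group means of miR-223 were −14.25 ± 0.91 with native HDL, −18.24 ± 0.41 with rHDL, −18.00 ± 0.27 with apoA-I, −17.91 ± 0.84 with SUV and −18.40 ± 0.84 with PBS (SD, n = 5, 5, 5, 4 and 4). The difference from SUV as deposited was lost in 8 of 9 fits that left out 1 sample (all but native HDL 5), with adjusted p up to 0.292. It was also lost with the replicate number as a block (3.55, adjusted p = 0.094 in limma). The difference from apoA-I held in 10 of 10 fits that left out 1 sample.

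Against rHDL, miR-146a (−2.05; −0.98 scaled) and miR-339-5p (−1.84; −0.78 scaled) were the lower assays with the smallest p in native HDL, and miR-23a (1.45; 2.16 scaled, and −0.65 without rHDL 2, rHDL 4 and native HDL 1) the other higher one. None of these 3 passed, and without rHDL 4 the former 2 were at −1.35 and −1.19. Against apoA-I, miR-17* was at 1.78 (1.75 scaled), miR-296-3p at −1.17 (−1.18 scaled) and miR-1276 at −1.07 (−0.70 scaled). Against SUV, miR-938 was at 2.67 (2.56 scaled, adjusted p = 0.2), miR-135a at −2.04 (−1.76 scaled) and miR-26a-2* at −1.61 (−1.72 scaled). With 1 sample left out miR-17* came to 0.77, miR-296-3p to −0.64, miR-1276 to −0.54, miR-135a to −1.03 and miR-26a-2* to −0.76.

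The structural comparisons gave no call in the main limma fit. Some other settings called miR-1293 or miR-376c in comparisons that include SUV, as given below. Adding phospholipid to apoA-I (rHDL against apoA-I, both at 1 mg/ml apolipoprotein A-I) changed 0 of 411 tested assays in limma, with 49 at an unadjusted p under 0.05 as deposited and 12 after scaling, and 0 by an ordinary 2-sample test. The counts of 49 and 12 are 11.9% and 2.92% of the assays, where chance gives 5% for independent assays. The median change was 1.11 as deposited and −0.03 after scaling, so the deposited count carries the shift of rHDL 2 and rHDL 4. The smallest p belonged to miR-32 (2.80; 1.44 scaled), miR-27a (2.25; 0.89 scaled), miR-1183 (−2.01; −2.10 scaled) and miR-624 (−0.93; −0.83 scaled). The phospholipid amounts of rHDL and SUV are not matched by the labels. rHDL against SUV changed 0 of 406 (16 at an unadjusted p under 0.05, 0 by an ordinary 2-sample test), led by miR-376c (3.25; 2.18 scaled), let-7b* (3.24; 2.36 scaled), miR-1293 (−7.34; −8.09 scaled) and miR-15a (−1.21; −2.08 scaled). apoA-I against SUV changed 0 of 406 (3 at an unadjusted p under 0.05, 0 by an ordinary 2-sample test), led by let-7b* (2.59; 2.28 scaled), miR-516-3p (2.63; 2.56 scaled, and 0.57 without SUV 5), miR-1293 (−8.29; −8.62 scaled) and miR-32 (−1.48; −1.19 scaled). The departure of rHDL from the sum of its components passed in 0 of 401 assays (13 at an unadjusted p under 0.05), led by miR-376c (3.70; 2.10 scaled), miR-133a (3.37; 1.66 scaled), miR-1293 (−6.23; −6.58 scaled) and miR-1276 (−1.20; −1.15 scaled). The median departure was 1.30 as deposited and 0.02 after scaling. The miR-1293 and miR-376c values rest on SUV 4 and SUV 5: in rHDL against SUV, miR-1293 was at 2.18 without SUV 4 and miR-376c at 1.17 without SUV 5. Leaving out 1 sample also brought miR-624 to −0.30, miR-15a to −0.59, miR-32 in apoA-I against SUV to −0.73, miR-1276 in the departure to −0.68 and let-7b* to 1.69 in rHDL and 1.28 in apoA-I against SUV. The median 95% interval of an assay in rHDL against apoA-I reached 1.66 log2 units to each side as deposited and 0.93 after scaling, so 2-fold differences of single assays were not excluded for most assays.

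Presence against absence was tested for the assays measured in part of the samples. None passed Fisher's exact test (adjusted p = 1 in all 4 treatments, from 186 to 206 assays each). The smallest p these group sizes allow is 0.00794, or 0.0286 with SUV (exact), so a single assay could not have passed after adjustment whatever its pattern. At unadjusted p, miR-363 was measured in 4 of 5 native HDL and 0 of 4 PBS samples (p = 0.0476, exact, 2-sided), and miR-141 and miR-373 in 0 of 5 and 3 of 4 (p = 0.0476, exact). miR-1256 was measured in 4 of 4 PBS samples, 1 of 5 with rHDL (p = 0.0476, exact) and 0 of 4 with SUV (p = 0.0286, exact). miR-96 was measured in 0 of 5 with apoA-I and 3 of 4 with PBS (p = 0.0476, exact).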

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

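The tests of the causes of the miR-223 difference, of the identical files and of the samples with a shifted level, and the repeat of the same splits after scaling, were chosen after these results were seen, while the counts over other splits of the samples were planned. Of 122 groups of samples examined, 18 (14.8%) had a gap ratio past Dixon's value. Chance gives 5% for continuous values, but these values lie close to steps of 1 cycle, so that share is no measure here.

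miR-223 was higher with native HDL than with PBS by 3.90 log2 units. A shift of a sample's or card's reference as the whole cause is argued against by the interval after card-mean scaling, whose lower end is 3.16. Whole blood cells or all of their RNA, carried in with the HDL preparation, could not be judged from 3 low markers measured with PBS. The limit on their distance from miR-223 was set after the results, and no levels of blood cells were available. Of the 3, miR-451 and miR-144* are on the erythroid list, which leaves only miR-142-3p from the myeloid and lymphoid list. miR-363 of the erythroid list had no PBS value and was not among them, and with native HDL its scaled mean of −18.80 was nearer to miR-223. With native HDL every measured value of miR-142-3p (scaled mean −21.18, 3 of 5 samples), miR-451 (−21.23, 2 of 5) and miR-144* (−21.25, 1 of 5) lay at least 6.01 cycles below miR-223 of the same sample (mean −14.25). Blood-derived RNA of another make-up stays open (0 of these 3 markers could be tested against PBS, and miR-363 of the erythroid list, in 4 of 5 native HDL and 0 of 4 PBS samples, goes with it, but was in 3 of 5 with rHDL), as does transfer of the whole HDL-associated set: without miR-223 the list had an adjusted p of 0.901, but only 1 of its tested members, miR-375, lies below the PBS level of miR-223, and it was at 2.14 scaled (interval 0.48 to 3.80, adjusted p = 0.996), which goes with transfer, but also at 1.60 scaled with rHDL, and at −0.18 as deposited without values near the lowest. A rise of miR-223 made by the endothelial cells, or its delivery by the native particle, was not tested, since the values count the microRNA whatever its origin.

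PBS 1 and SUV 1 held 420 equal values of 420 measured. This is consistent with 1 set of measurements deposited under both labels, and which label is right cannot be told from these values.

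The lowest log2 value of a sample was high in native HDL 1 (−18.71, next −23.16, gap ratio 0.821) and in rHDL 4 (−17.22, next −22.28, gap ratio 0.733), which also had the fewest assays measured in their groups (363 and 361). A later threshold cycle of the reference together with less RNA could give both. Over 23 samples the lowest value and the number of assays measured had a Pearson r of −0.860 (permutation p = 1e-05, the smallest that 100000 permutations give, adjusted p = 2e-05) and a Spearman rho of −0.471 (permutation p = 0.0235, adjusted p = 0.0235). Without these 2 samples, the farthest from the median, r was −0.637 (permutation p = 0.0037) and rho −0.304 (permutation p = 0.176), so the rank relation rests on them and the explanation cannot be told apart from others. No biological explanation was tested.

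In 6 assays the sample with a gap ratio past Dixon's value lay more than 1 step from the next. These were miR-23a* (native HDL 5, −20.10 against −17.25, ratio 0.942), miR-222 (native HDL 1, 0.33 against −2.11, 0.7101), miR-938 (native HDL 1, −16.11 against −18.26, 0.716), miR-187 (PBS 2, −16.13 against −18.07, 0.936), miR-432* (SUV 5, −22.79 against −15.32, 0.962) and let-7b* (apoA-I 4, −10.00 against −13.07, 0.919). In 10 others the sample was about 1 step from the next, the resolution of a value, so that it was not far from the others, and the ratio is high because the rest lay close together. These were miR-885-5p (native HDL 5, −20.25 against −19.19, 0.941), miR-1276 (native HDL 2, −21.12 against −20.25, 0.850), miR-296-3p (PBS 5, −18.16 against −17.18, 0.918), miR-654-5p (PBS 5, −14.13 against −13.16, 0.854), miR-216a (PBS 5, −14.12 against −13.17, 0.873), miR-146a (PBS 3, −7.05 against −6.17, 0.942), miR-1227 (PBS 2, −16.20 against −15.16, 0.945), miR-376c (PBS 4, −10.17 against −11.06, 0.919), miR-126 (SUV 4, −1.18 against −0.22, 0.857) and miR-148b* (SUV 5, −13.90 against −15.11, 0.872). Among assays that did not enter the tests, miR-199b-5p and miR-548K were each measured in 3 of 5 rHDL and 0 of 4 PBS samples, but also in 2 and 1 of 5 with native HDL, 2 and 1 of 5 with apoA-I and 2 of 4 each with SUV.

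Splitting the same samples in other ways tested how often chance gives as many assays past the threshold. The planned limit was a share of 0.05 of the splits, without adjustment over comparisons. For native HDL against PBS the share was under the limit as deposited (1 assay, 2 of 100 splits as many, highest other 1). After card-mean scaling it was not (1 assay, 6 of 100, highest other 1). For native HDL against apoA-I it was under the limit with both scalings (1 assay, 1 of 100, highest other 0). In native HDL against SUV it was over the limit as deposited (1 assay, 22 of 100, highest other 2). After scaling it was under it (1 assay, 3 of 100, highest other 1). For native HDL against rHDL it was not under the limit after scaling (1 assay, 5 of 100, highest other 11). A share under the limit does not exclude chance, and the count takes no account of the size of a change. The other comparisons had 0 assays past the threshold in limma, so every split gave as many by construction and the splits test nothing there: rHDL against PBS (100 of 100, highest other 2), apoA-I against PBS (100 of 100, 0), SUV against PBS (35 of 35, 1), rHDL against apoA-I (100 of 100, 150), rHDL against SUV (100 of 100, 148), native HDL against rHDL as deposited (100 of 100, 268), apoA-I against SUV (100 of 100, 1) and the departure of rHDL from its components (100 of 100, 1). The assays at an unadjusted p under 0.05 numbered 2, 1, 5, 49, 16, 19, 3 and 13 in that order, and an ordinary 2-sample test called 0, 0, 1, 0, 0, 0 and 0 in the first 7. Splits that call 148, 150 or 268 assays point to a structure of the samples. With the same splits after card-mean scaling the highest were 1, 1 and 11, so most of it lies in shifts of whole samples or cards.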

How the results depend on the processing

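Card-mean scaling, the treatment of the identical files, of the lowest and missing values and of the doubted samples (rHDL 2, rHDL 4, native HDL 1), and their combinations were tests chosen after seeing the data. Limits of 32, 37 or 40 on the threshold cycle and small-RNA controls could not be run without such values. Of 252 counts over 11 comparisons 228 were the same and 24 changed. The settings with no further normaliser and with undetermined wells left missing are the main fit itself. Their counts and values, here and below, were the same by construction. Of 1952 values of named assays (88 pairs of assay and comparison, besides miR-223 in native HDL against PBS, given below) 1858 kept side and sign, 4 lost (miR-223 in native HDL against SUV) and 18 gained a call, and 72 reversed, none of them called. The cause of each change below was not tested, except where fewer samples or another scaling is itself the change.

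miR-223 in native HDL against PBS passed in 21 of 23 settings (3.46 to 4.42, adjusted p 3.15e-07 to 0.743). Those that repeat the main fit are among the settings passed and add no support. It lost its call, with the count at 0, by the ordinary 2-sample test (3.90, adjusted p = 0.743; 3 assays at an unadjusted p under 0.05, where limma called 1) and with missing values at the sample's lowest (3.90, adjusted p = 0.0579). Leaving out 1 sample gave 0 to 1 assays and 3.46 to 4.49 for miR-223 over both scalings. The labels do not say what a replicate number stands for. Of 43 pairs of samples with the same number in different groups, 21 deviated together with a correlation above 0.1 (median 0.099, from −0.431 to 0.809, against a median of −0.059 in 168 other pairs), and 10 of 23 samples correlated best with their own number, a hint of shared deviation that not every pair shows. Only rHDL and apoA-I had all 5 pairs above 0.1 (0.211 to 0.809), and there the block left the count at 0. With the number as a block miR-223 was at 3.78 (adjusted p = 0.0346), and of 11 counts 6 were the same and 5 changed.

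For SUV against PBS the block gave 1 (miR-1293) and the ordinary test 1 (miR-26a-2*). For rHDL against SUV assays measured in all samples gave 1 (miR-376c), the block 2 (miR-1293, miR-376c) and only the groups compared 1 (miR-1293). For native HDL against rHDL, 1 (miR-223) was called with medians per card, quantiles, 1 mean over both cards, card means, values within 3 cycles of the lowest left out, without the doubted samples and in 4 combinations with card means. For native HDL against apoA-I the ordinary test gave 2 (miR-223, miR-432*). For native HDL against SUV 0 were called with assays measured in at least 1 sample (adjusted p of miR-223 0.0883), the block (0.094), the ordinary test (0.389) and missing values at the lowest (0.121). For apoA-I against SUV and the departure of rHDL from its components the block gave 1 each (miR-1293). Leaving out 1 sample gave 0 to 1 in native HDL against rHDL and against SUV. Of 3 list calls, an estimated correlation, fry, fry in either direction and card means without miR-223 left 0, while fry in either direction on card means called 4 (HDL-associated, NF-kB, lipid and blood cells with native HDL, each holding miR-223). The block and leaving out miR-223 left 1 (DLK1-DIO3), card means with an estimated correlation or fry 1 (blood cells), and leaving out 1 sample 1 to 4.

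Sign changes, for rHDL against PBS: miR-126 −0.69 and miR-21 −0.51 with medians, −0.47 and −0.82 with quantiles, −0.67 and −0.50 with 1 mean, −0.66 and −0.48 with card means (also with missing at the lowest), −0.56 and −0.65 with card means and block, −0.61 and −0.43 with card means and all 25 samples, −0.23 and −0.25 with card means without the doubted samples. With missing at the lowest: miR-638 1.11, miR-1183 0.14, miR-374a* 0.54, miR-486-3p 1.02, and with card means miR-638 0.24 and miR-486-3p 0.20. Without the doubted samples: miR-182 −0.46 (−0.18 with card means), miR-223 −0.35, miR-126 −0.62, miR-146a −0.0233, miR-21 −0.63, miR-222 −0.10.

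For apoA-I against PBS: miR-223 0.23 and miR-146a 0.21 with medians, 0.60 and 0.44 with quantiles, 0.16 and 0.15 with 1 mean, 0.40 and 0.39 with card means (also with missing at the lowest or without the doubted samples), 0.40 and 0.58 with card means and all 25 samples, 0.33 and 0.37 with card means and block (miR-126 0.0426), 0.00646 and 0.19 with all 25 samples or the identical file as PBS; miR-222 −0.0473 with the block.

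For SUV against PBS: miR-222 0.13 with medians, 0.24 with quantiles, 0.14 with 1 mean, 0.24 with card means (also with block or missing at the lowest), 0.19 with all 25 samples besides, 0.25 without the doubted samples besides, 0.0873 with the identical file as PBS. With missing at the lowest miR-601 was −0.89, miR-661 0.086 and miR-432* 0.0626 (−0.93, 0.0465 and 0.0231 with card means). In native HDL against PBS miR-222 was 0.26 with medians and miR-375 −0.18 without values near the lowest. miR-624 was 0.45 in rHDL against apoA-I without values near the lowest, miR-15a 0.60 in rHDL against SUV with assays measured in all samples, and miR-23a −0.65 (−0.55 with card means) in native HDL against rHDL without the doubted samples.

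Leaving out 1 sample reversed 27 of 827 values, over these ranges. Against PBS: miR-222 −0.81 to 0.0555 with native HDL; miR-126 −0.27 to 0.45 and miR-21 −0.0421 to 0.67 with rHDL; miR-1282 −0.0752 to 1.63, miR-223 −0.42 to 0.28, miR-146a −0.51 to 0.26 and miR-222 −0.25 to 0.51 with apoA-I; miR-223 −0.0403 to 0.66, miR-222 −0.53 to 0.51, miR-432* −2.37 to 0.22 and miR-1293 −2.33 to 12.32 with SUV. miR-1293 ran from −12.47 to 2.18 in rHDL against SUV, −13.43 to 1.22 in apoA-I against SUV and −11.37 to 3.28 in the departure, and miR-23a from −1.19 to 2.03 in native HDL against rHDL.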

Other observations

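Some single values lay far from those of the same assay in other samples. miR-519b-3p had a log2 level of 8.42 in apoA-I 1 against a median of −22.13 elsewhere, and miR-1293 one of 8.56 in SUV 4 against −18.15, both above the most abundant microRNA of the cells. SUV 5 held low values of miR-661, miR-376c and miR-149* (−22.78 against −13.57), besides miR-432*. The highest values of SUV 5 and native HDL 2 were those of miR-448 (9.66) and miR-885-3p (7.20).

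The passenger strand miR-223* was measured in 0 samples of any group. miR-573, another member of the HDL-associated list, was measured in 2 of 5 native HDL samples (scaled mean −16.72) and 1 of 4 PBS samples (−19.61), too few for a test. It was also measured in 2 of 5 samples with apoA-I, 1 of 5 with rHDL and 0 of 4 with SUV. miR-105 was measured in none.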
